A study of Desulfovibrio ferrophilus with 2 samples.

How the data were processed

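Total RNA of 2 cultures of Desulfovibrio ferrophilus IS5 was depleted of ribosomal RNA and sequenced, with 1 library per medium, per the labels' protocols. Cells were pelleted by centrifugation in an anaerobic chamber and placed in an RNA preservative before extraction, per the labels. The groups 195c and EASW and the ferrous iron concentrations were taken from the sample labels and the series design text. Pairing was not possible with 1 library per group.

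The values used were CPM per gene (reads scaled to a common total per library), as deposited by the authors in 1 table, per the file headers. Each column of the 3368 listed genes adds up to the full CPM total. The authors also deposited a column headed as a fold change, which holds log2 ratios: it equalled log2 of EASW CPM over 195c CPM, with no pseudocount, in 3362 cells, and 6 cells were spreadsheet errors. That column was checked and not used further. STAR is named in the submitters' processing notes. Its version, the counting tool, the strand setting and the genome build are not given in the sources used here, so reads shared between near-identical or overlapping genes, or between strands, could not be separated. Locus names, symbols, products and coordinates (counted from 1) were taken from the deposited table, which gives a symbol for 653 genes. It lists 3295 protein-coding genes, 61 tRNA genes, 6 rRNA genes and 6 pseudogenes, 3319 of them on the larger replicon and 49 on the smaller.

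Every CPM value lay within 0.01 reads of a whole multiple of 1 read, taken as 0.0931 CPM in the 195c library and 0.114 CPM in the EASW library. The totals that follow are 10741422 and 8782535 reads. These read numbers rest on the spacing of the values and were used only for intervals and for the weights of the trimmed mean, and no count model was fitted. A ratio has an exact conditional binomial 95% interval and a level an exact Poisson 95% interval. Both cover counting error only, not differences between cultures or preparations, and reads without molecular identifiers are not independent molecules. A count of 0 was taken to allow up to 3 reads, a fixed value and not the bound of the Poisson interval above. That is 0.279 CPM in the 195c library and 0.342 CPM in the EASW library.

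Log2 ratios were taken as log2 of CPM plus a pseudocount of 1, EASW over 195c, a scale that understates differences of low genes. With no replicates, a fixed rule of size stood in place of a test. A gene was counted as higher or lower at a ratio of at least 2-fold, among 3092 genes with a mean CPM of at least 20. There were 31 gene lists fixed by symbol and product name before the data were examined, of which 29 had members. For each, the median over members with a mean CPM of at least 5 was given as a percentile among 10000 random lists of the same size, drawn gene by gene and matched on mean CPM in 20 bins. A list stood apart at a percentile of at most 2.5 or at least 97.5. Over 29 lists, 1.45 would do so by chance if lists were random draws of independent genes, which neighbours in an operon are not. After the table was opened, 24 false matches were taken out of the lists on their product names, at a point when values of part of the sulfate reduction list had been seen; the lists with those members were run as an alternative. The lists overlap: cytochrome, ferredoxin and sulfate reduction lists share some genes.

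The genes named were fixed by rule before the data were examined. They are the 10 highest and 10 lowest log2 ratios with a named product and the 3 highest and 3 lowest without one (mean CPM of at least 20), up to 4 members of each list with the largest absolute ratio, the 5 genes of highest CPM in each library, and every measured gene of the outer-membrane cytochrome and ferrous iron uptake lists. The rule gave 143 genes, of which a part is printed. Genes named in the closing observations and there said to be outside the rule were chosen after their values were seen.

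Alternatives fixed beforehand were pseudocounts of 0.1 and 5 CPM, no filter, a mean CPM of at least 100, a 4-fold threshold, the rule on the interval bound nearest to no change, centring on the median gene, a trimmed-mean scaling (30% of ratios and 5% of levels trimmed at each end), totals without stable RNAs and the 10 most abundant genes, circular shifts of a list along the gene order, the mean of a list, and 1 value per run of neighbouring members (at most 3 rows apart). Alternatives chosen after seeing the data were a background per kb at the 1st or 5th percentile of protein-coding genes taken off in each library, the lists before removal of false matches, random lists matched on the 195c level per kb, that matching together with 1 value per run, and runs placed at 1000 random positions. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

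The calculations were tested on simulated data for EASW against 195c, with reads drawn for the 3368 genes and 200 of them changed. The 2-fold rule found 94.0% of 50 genes changed 3-fold, 96.0% of 50 changed 4-fold and 98.0% of 50 changed 8-fold, and it took 0 of 2878 unchanged genes. The 95% interval held the true ratio in 95.2% of 1000 unchanged genes. The list rule was tried on the log2 ratios of the 2 libraries themselves, not on simulated reads. Of 200 random lists of 20 genes, 6.00% passed the percentile rule, and 98.5% did after a shift of 2 on the log2 scale. These lists were drawn gene by gene, as the random lists of the rule are, so a low pass rate follows from the drawing. It says nothing about lists of neighbouring genes. The simulated reads hold counting error only. Sequence composition and the reference genome were not analysed here.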

Results

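The data described RNA of the sulfate-reducing bacterium Desulfovibrio ferrophilus strain IS5 after 4 days of growth in either of 2 media. DSMZ medium 195c held 7.6 µM ferrous iron and the iron-enriched medium, named EASW in the labels, held 3.6 mM. The comparison asked how elevated ferrous iron goes with gene expression, but the media carry different names and may have differed in more than iron. There was 1 library per medium, so no spread between replicates could be had, no test was run between the media, and no p-value is given. The 195c column corresponded to 10741422 reads and the EASW column to 8782535 reads over 3368 genes. Ratios below are EASW over 195c as log2 of CPM plus 1, folds are of CPM itself, and the intervals are 95% intervals that cover counting error only.

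Gene expression differed widely between the libraries. The lowest ratios of all belonged to a pair of neighbouring ferrous iron transport genes, and the highest to a gene for a universal stress protein, a family known to be made under growth arrest and stress. Of 3092 genes with a mean CPM of at least 20, 952 (30.8%) were at least 2-fold higher in the EASW library, 903 (29.2%) were at least 2-fold lower and 1237 lay between. Of the fixed gene lists, 6 lay below the range of random lists matched on expression, among them ribosomal proteins, ATP synthase and sulfate reduction, and 4 lay above it, among them prophage genes and flagellum and chemotaxis. With 1 value per run of neighbouring genes, 2 of the 6 (ribosomal proteins and amino acid biosynthesis) and 2 of the 4 (prophage genes and signalling) kept their place; with those runs compared with runs placed at random, 4 of the 6 and 2 of the 4 did. With 1 value per run and random genes matched on the 195c level, ribosomal proteins (percentile 12.1) and prophage genes (93.3) also lay inside the range. A percentile among random lists is a description of these 2 libraries. The Spearman correlation of CPM between the libraries, taken across genes, which are not independent replicates, was 0.590. With a threshold of 4-fold the counts were 458 higher and 436 lower, and with a mean CPM of at least 100 the higher count was 592. A trimmed-mean scaling moved every log2 ratio by 0.20 downward and gave 845 higher and 1006 lower.

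**Figure D1:**
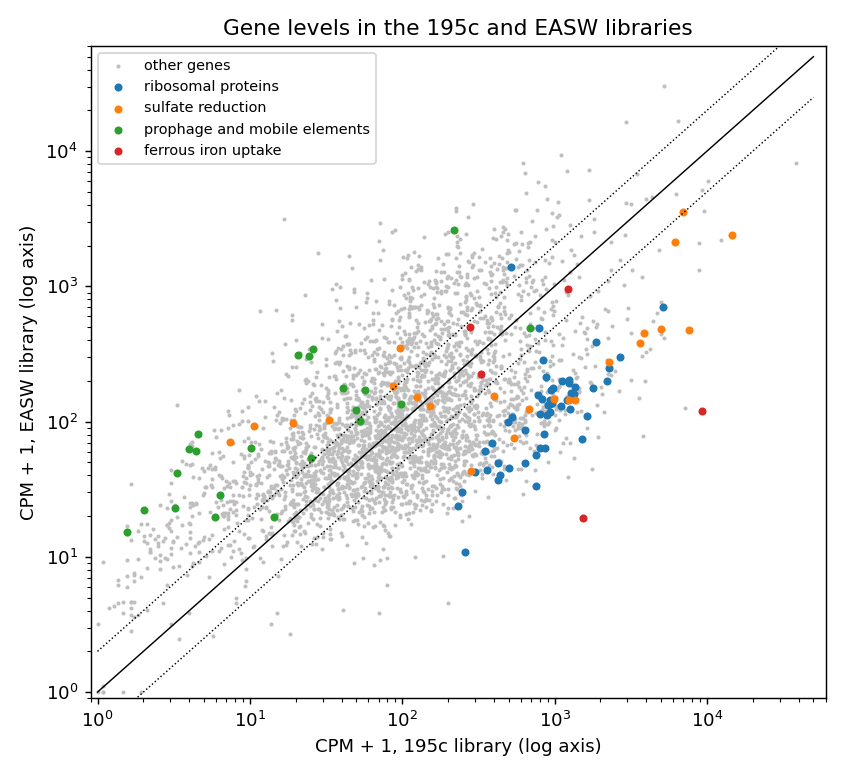
CPM plus 1 of each gene in the 195c library (horizontal log axis) against the EASW library (vertical log axis), 1 point per gene, with the solid line at equal values and dotted lines at 2-fold. Coloured points are 4 of the fixed gene lists; 50 of 52 ribosomal protein genes and 14 of 23 sulfate reduction genes were at least 2-fold lower in the EASW library, and 18 of 22 prophage and mobile element genes were at least 2-fold higher.

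The ferrous iron uptake genes fell into 2 loci with different ratios. FeoA and FeoB form the main bacterial importer of ferrous iron, FeoB being its membrane pore. The feoB gene DFE_1866, at 1990988 to 1993174 on the plus strand of the larger replicon, stood at 9278 CPM in the 195c library and 119.8 CPM in the EASW library, 77.5-fold lower (72.9 to 82.4). Its upstream neighbour DFE_1865, a ferrous iron transport protein A gene at 1990742 to 1990984, stood at 1527 and 18.4 CPM, 82.8-fold lower (70.9 to 97.3). In EASW, DFE_1866 and DFE_1865 stood at 54.8 and 75.9 CPM per kb of annotated length. The 5th percentile of protein-coding genes there was 30.5, so the size of both folds depends on any background of reads. The second locus lay on the minus strand, where feoB of DFE_3369 (3668299 to 3670485) had 1231 CPM in 195c and 963 CPM in EASW, a fold of 0.782 (0.761 to 0.804). DFE_3370, of the FeoA family, had 278 and 497 CPM, and DFE_3371 had 329 and 225 CPM. None of these 3 genes differed by 2-fold. The median log2 ratio of the 5 genes was -0.54, at percentile 31.1 of random lists, because 3 of the 5 members lay in the second locus. By its mean, -2.52, and among runs placed at random, the list lay below the range.

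Other iron-related lists lay inside the range of random lists. Of 9 ferric iron and siderophore uptake genes, 2 were at least 2-fold higher and 3 lower (median -0.42, percentile 22.8), and the TonB-dependent receptor DFE_3100 was lower, at 569 and 122 CPM. Among the 3 metal-dependent repressors (median 0.44, percentile 67.3), the Fur family gene DFE_2329 was higher with a log2 ratio of 1.19, DFE_1966 was lower with -1.88 and DFE_3344 had 0.44. DFE_2329 had 0.99 after trimmed-mean scaling, just under the 2-fold rule. Of 5 iron-sulfur cluster assembly genes, 2 were higher, 1 was lower and the median was 0.98 (percentile 72.0); the scaffold gene nifU (DFE_3228) had 608 and 1438 CPM. No gene in the table matched the iron storage list.

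**Figure D2:**
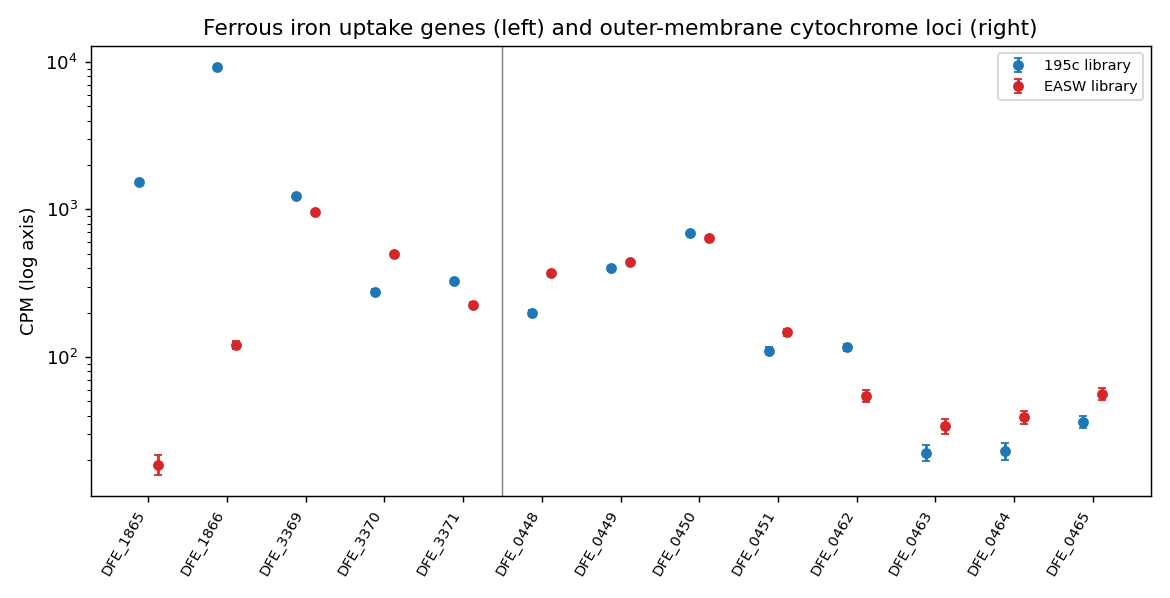
CPM (vertical log axis) of the 5 ferrous iron uptake genes, left of the line, and the 8 measured genes of the outer-membrane cytochrome loci, right of it, in the 195c library (blue) and the EASW library (red). Bars are 95% Poisson intervals that cover counting error only; feoB DFE_1866 stood at 9278 and 119.8 CPM, and of the other genes shown DFE_1865 and DFE_0462 were at least 2-fold lower in EASW.

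The 2 outer-membrane cytochrome loci, which carry multihaem cytochromes of the kind that move electrons out of the cell, were close in the libraries. Of 8 measured genes, 7 differed by less than 2-fold and the median log2 ratio was 0.49 (percentile 69.7). DFE_0448 to DFE_0451 had log2 ratios of 0.89, 0.15, -0.11 and 0.40, and DFE_0463 to DFE_0465 had 0.58, 0.74 and 0.62. The cytochrome gene DFE_0462 was the exception, 2.13-fold lower (1.91 to 2.37) at 115.9 and 54.5 CPM. Levels were low in the second locus, where DFE_0464 had 22.9 CPM in 195c and 38.9 CPM in EASW. With the 5th percentile of CPM per kb taken off in each library as a background, its log2 ratio was -1.06. DFE_0462, DFE_0463 and DFE_0465 stood at 43.9, 37.7 and 48.4 CPM per kb in EASW, against 30.5 taken off there. Their ratios depend on the background too.

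The list of c-type cytochromes went both ways. Of 34 genes, 10 were at least 2-fold higher in the EASW library and 16 lower (median -0.08, percentile 16.5). The lowest were in the hmc operon, which encodes a transmembrane redox complex between periplasmic cytochromes and the cytoplasm. The cytochrome gene hmcA (DFE_3365, 3662292 to 3663911) stood at 3786 and 76.9 CPM, 49.3-fold lower (45.6 to 53.2). Its neighbours hmcB, hmcC, hmcD and hmcE (DFE_3364 to DFE_3361) had log2 ratios of -5.30, -4.64, -5.47 and -4.97. Of these, hmcB, hmcD and hmcE count in the list although their products are not named as cytochromes. In EASW hmcA and hmcD stood at 47.4 and 24.5 CPM per kb, near the floor of that library (5th percentile 30.5). Higher genes included the multihaem cytochrome locus DFE_1890 to DFE_1892, chosen after its values were seen, with a median of 3.11 and a summed 22.8 and 204 CPM. At such low levels the ratios of that locus depend on any background of reads. Among the 21 genes of the list with a mean CPM of at least 100, 15 were lower and 4 higher, with a median of -2.64 (percentile 0). Cytochrome c maturation genes had a median of -1.21 (percentile 0.590; 5 of 8 lower), with DFE_0907 at -1.77 and DFE_1646 at -1.63. DFE_2049, named a cytochrome c assembly protein, went the other way, 65.1-fold higher (57.9 to 73.4) at 27.0 and 1757 CPM. The maturation list no longer stood apart with circular shifts along the gene order (percentile 10.1), with the mean of the list (17.2) or with 1 value per run of neighbours (10.4).

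Genes of dissimilatory sulfate reduction, the respiration of this organism, went both ways, with the operons of the core enzymes lower in the EASW library. Of 23 genes, 14 were at least 2-fold lower and 6 higher, with a median log2 ratio of -2.45 (percentile 0.01). That call rested on neighbouring genes: with 1 value per run of neighbours, 13 runs had a median of 0.28 and a percentile of 59.9. Sulfate adenylyltransferase (sat, DFE_2054), which activates sulfate, stood at 7631 and 476 CPM, a log2 ratio of -4.00. The adenylylsulfate reductase gene aprA (DFE_2056) had 14694 and 2396 CPM. The sulfur relay gene DFE_0248 and the pyrophosphatase gene DFE_0854 were 10.3-fold and 9.52-fold lower. The drop was smaller for dsrAB and D (DFE_3070 to DFE_3072), which are outside the naming rule. They were 1.93-fold to 2.92-fold lower, 2 of the 3 by at least 2-fold, with a summed 13508 and 5850 CPM. The higher members included sulfate transporter genes such as DFE_0984, at 6.42 and 69.9 CPM. In CPM per kb DFE_0984 stood at 3.87 and 42.1, against 5th percentiles of 11.5 in 195c and 30.5 in EASW. Its ratio therefore depends on any background of reads.

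Among other lists of energy metabolism, ATP synthase and formate dehydrogenases stood apart and the other 4 lay inside the range. All 9 ATP synthase genes were lower, with a median of -3.49 (percentile 0) and atpE (DFE_2906) 18.2-fold lower (17.1 to 19.4); they lay in 2 runs, whose values gave a percentile of 2.95 among single genes and 0.1 among runs placed at random. Of 15 hydrogenase genes, 9 were lower and 2 higher (median -1.14, percentile 2.64), with hypB (DFE_0700) at -2.56 and the small subunit gene DFE_2826 at -3.01. Of 9 formate dehydrogenase genes, 7 were higher and 1 lower (median 1.90, percentile 98.4), with fdnG of DFE_1352 at 23.7 and 154 CPM. In CPM per kb fdnG stood at 7.83 and 50.9, against 5th percentiles of 11.5 in 195c and 30.5 in EASW. Its ratio therefore depends on any background of reads. The higher accessory protein gene DFE_0635 stood well above those percentiles, at 262 and 1164 CPM per kb. The formate dehydrogenase call was lost with a mean CPM of at least 100 (percentile 94.4), though the median of 1.74 was close to that of all 9 genes. It was also lost with 1 value per run (96.3, but 98.7 among runs placed at random) and with random lists matched on the 195c level (87.4). Of 14 genes of lactate, pyruvate and acetate metabolism, 8 were lower and 1 higher (median -1.07, percentile 6.28), among them pyruvate oxidoreductase nifJ (DFE_3289) at 12273 and 2184 CPM. The 8 genes of alcohol and aldehyde oxidation had a median of 0.22 (percentile 58.2), and the aldehyde ferredoxin oxidoreductase DFE_2741 was 19.6-fold lower (18.6 to 20.5). The 30 ferredoxins, flavodoxins and rubredoxins had a median of 0.06 (percentile 36.0), 8 of them higher and 12 lower.

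Genes of the translation and biosynthesis machinery were more often lower than higher in the EASW library. Of 52 ribosomal protein genes, 50 were at least 2-fold lower and 1 higher, with a median of -2.97 (percentile 0; 12.1 with 1 value per run matched on the 195c level). The genes rpmB (DFE_2213), rpsU (DFE_1061) and rpsI (DFE_1848) were 26.3-fold, 23.3-fold and 20.4-fold lower. Of 73 amino acid biosynthesis genes, 44 were lower and 5 higher (median -1.54, percentile 0), with the acetolactate synthase gene ilvB (DFE_0524), of branched-chain amino acid synthesis, at 1080.0 and 58.6 CPM. Of 35 haem and corrin biosynthesis genes, 18 were lower and 5 higher (median -1.02, percentile 0.700). There hemB (DFE_1923) was at -2.81 and cobM (DFE_3286) at 3.24, and 1 value per run gave a percentile of 2.87, or 0.5 among runs placed at random. Of 26 chaperones and proteases, 12 were lower and 5 higher (median -0.71, percentile 7.85), with groL (DFE_3110) at 8858 and 1323 CPM.

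**Figure D3:**
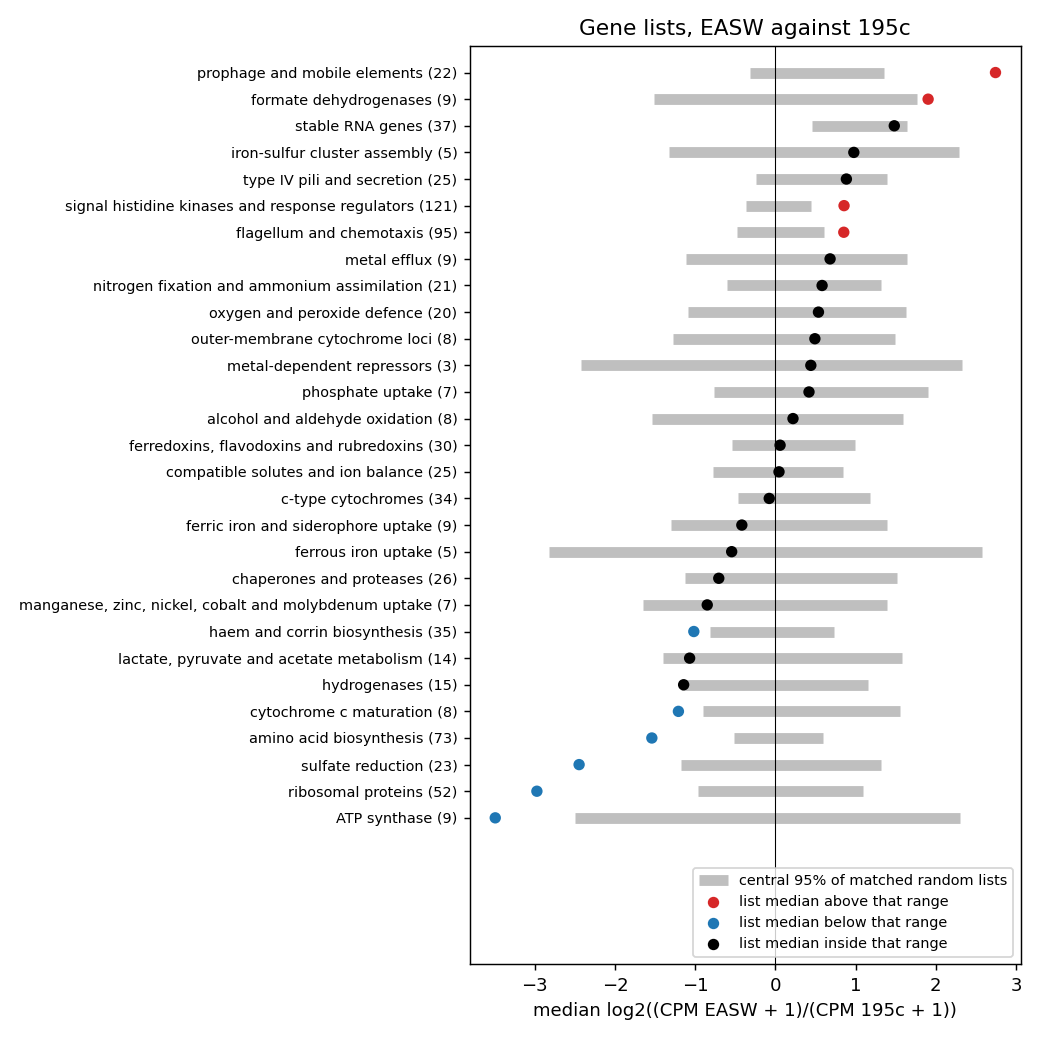
Median log2 ratio of each fixed gene list (points, with the number of measured genes in brackets) and the central 95% of medians of 10000 random lists matched on mean CPM (grey bars). Medians ran from -3.49 for ATP synthase to 2.74 for prophage and mobile elements.

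Motility and signalling genes were more often higher than lower in the EASW library. Of 95 flagellum and chemotaxis genes, 45 were at least 2-fold higher and 7 lower (median 0.85, percentile 99.9). With 1 value per run of neighbours the percentile of this list was 94.8, and 93.7 among runs placed at random, both inside the range. The anti-sigma factor gene flgM (DFE_1177) stood at 223 and 3628 CPM. DFE_2105, a gene for flagellin, the filament subunit, stood at 2921 and 16506 CPM, 5.65-fold higher (5.58 to 5.72). Of the 7 flagellin genes, a set outside the naming rule, 4 were at least 2-fold higher and 1 lower. Of 121 signal histidine kinases and response regulators, 54 were higher and 13 lower (median 0.86, percentile 99.98); with runs of neighbours placed at random the percentile was 97.2, inside the range. The response regulator DFE_1896 was 15.9-fold higher (15.0 to 16.9), while divK of DFE_3357 was 18.6-fold lower. DFE_3357 lies close to the hmc operon on the same strand, so its drop and that of the operon may not be separate findings. Type IV pili and secretion genes had a median of 0.89, inside the matched range (percentile 76.0), with 12 of 25 higher and 3 lower.

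Prophage and mobile element genes had the highest median of any list, 2.74 (percentile 100; 93.3 with 1 value per run matched on the 195c level), with 18 of 22 at least 2-fold higher and none at least 2-fold lower. The portal protein gene DFE_1737 was 15.6-fold higher (13.6 to 18.1) at 19.8 and 310 CPM. The primase gene DFE_1746 was 22.5-fold higher (16.3 to 32.1) at 3.54 and 79.7 CPM. All members named by rule lay in the same region, DFE_1720 to DFE_1746. In that region, which is outside the naming rule, 24 of 25 genes were at least 2-fold higher, so the list does not stand for independent loci. Most members were low in the 195c library, and the floor of gene levels differed between the libraries. The 1st percentile of protein-coding genes was 3.74 CPM per kb in the 195c library and 21.8 CPM per kb in the EASW library, and the 5th percentile was 11.5 and 30.5 CPM per kb. There were 297 protein-coding genes under 20 CPM per kb in the 195c library and 22 in the EASW library.

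**Figure D4:**
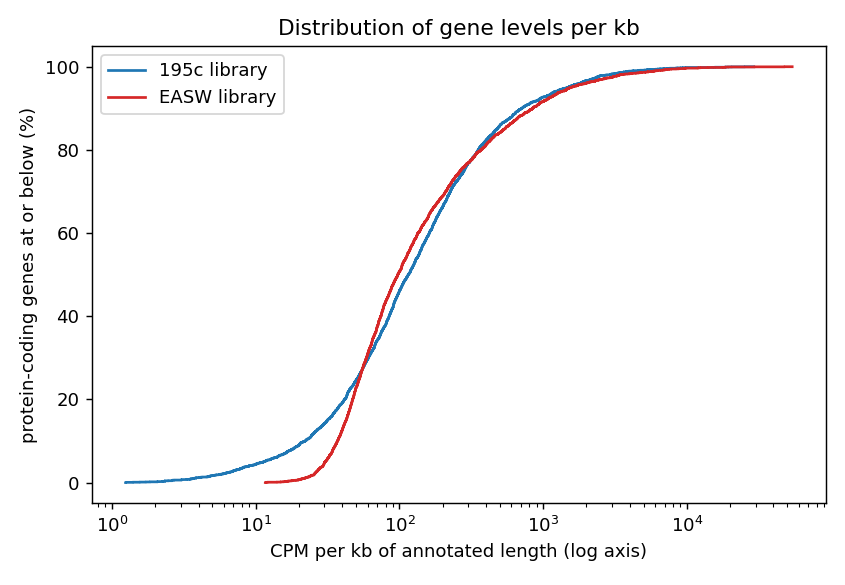
Cumulative distribution of CPM per kb of annotated length (horizontal log axis) over protein-coding genes in the 195c library (blue) and the EASW library (red); the vertical axis gives the percent of genes at or below each level. The lowest gene stood at 1.24 CPM per kb in 195c and at 11.6 CPM per kb in EASW.

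The genes with the highest ratios had products of several kinds. The highest of all was that of the UspA gene DFE_2459 (2637049 to 2637471, minus strand), at 15.7 and 3164 CPM, 201-fold higher (173 to 235). The hemerythrin-like gene DFE_2822 was 39.2-fold higher (34.4 to 44.8). The UspA gene DFE_0048 was 31.0-fold higher (28.8 to 33.4), and the PnuC transporter gene DFE_2397 was 61.0-fold higher (50.7 to 74.0). Genes of oxygen and peroxide defence went both ways: of 20, 9 were higher and 6 lower (median 0.54, percentile 60.1). Methionine sulfoxide reductase msrB (DFE_0812) had 106.7 and 1619 CPM, whereas cydB (DFE_2917) of the cytochrome bd oxidase had 1302 and 122 CPM. Among the genes with the lowest ratios, the carbon starvation gene DFE_0117, a CstA homologue, was 57.5-fold lower (54.2 to 61.1).

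The remaining lists lay inside the range of random lists. Their medians and percentiles were 0.68 and 71.3 for metal efflux, -0.85 and 17.3 for manganese, zinc, nickel, cobalt and molybdenum uptake, 0.42 and 44.2 for phosphate uptake, 0.58 and 67.0 for nitrogen fixation and ammonium assimilation, and 0.05 and 53.9 for compatible solutes and ion balance. In the nitrogen list, the dinitrogenase cofactor gene DFE_1237 was the most abundant gene of the EASW library, at 30117 CPM against 5254 CPM in 195c, and nifH (DFE_1492) was at 4.00 and 42.2 CPM. The 37 measured stable RNA genes had a median of 1.48 (percentile 92.5), with tRNA-Ser DFE_t0017 at 2.33 and 133 CPM and tRNA-Thr DFE_t0004 at 68.9 and 2.85 CPM. The stable RNA list lay above the range with circular shifts and with 1 value per run, but at percentile 42.85 with no filter. Ribosomal RNA took 55.7 CPM in the 195c library and 309 CPM in the EASW library. The RNA had been depleted of ribosomal RNA, so these values do not give its level in the cells. The most abundant gene of the 195c library was the porin gene DFE_1517, at 38574 CPM against 8221 CPM in EASW. No gene was left in the CRISPR and restriction list.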

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

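Taking off a background, the lists before removal of false matches, matching on the 195c level (alone or by runs) and random placement of runs were chosen after the data were seen; the other alternatives were fixed before. No paired analysis was possible because each medium had 1 library. The count of genes higher in EASW (952) was 592 with a mean CPM of at least 100, where fewer genes were considered, and 458 with a 4-fold threshold, where the lower count (903) was 436. In the other alternatives run, the higher count lay between 845 and 1120 and the lower count between 648 and 1266, the last with the background of the 5th percentile taken off. The number of lists below the matched range was 6, 2 with 1 value per run of neighbours, and 3 with those runs matched on the 195c level.

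Which lists stood apart depended most on how neighbouring genes were treated. With 1 value per run, sulfate reduction moved to percentile 59.9 and turned direction (59.7 with runs placed at random). Neighbouring lower members such as sat (DFE_2054) and aprA (DFE_2056) share a run there, while the lower genes DFE_0248 and DFE_0854 lie apart from them. The same alternative gave 96.3 for formate dehydrogenases, 10.4 for cytochrome c maturation, 2.95 for ATP synthase, 94.8 for flagellum and chemotaxis and 2.87 for haem and corrin biosynthesis, all inside the range, and 98.9 for stable RNA genes, which then stood apart. Runs placed at random kept ATP synthase (0.1), haem and corrin biosynthesis (0.5) and formate dehydrogenases (98.7) outside the range, and gave 11.7 for cytochrome c maturation, 93.7 for flagellum and chemotaxis, 97.2 for signal histidine kinases and response regulators, 0 for ferrous iron uptake, 97.7 for oxygen and peroxide defence and 100 for stable RNA genes. Circular shifts gave 10.1 for cytochrome c maturation and 99.9 for stable RNA genes. The mean of the list gave 17.2 for cytochrome c maturation, 1.20 for hydrogenases, 0.630 for c-type cytochromes and 0.690 for ferrous iron uptake. A mean CPM of at least 100 gave 94.4 for formate dehydrogenases, 0 for c-type cytochromes and 1.05 for ferredoxins, flavodoxins and rubredoxins. Hydrogenases, at 2.64, passed the bound with a pseudocount of 5 CPM (2.23), with no filter (2.23) and without stable RNAs and the 10 most abundant genes (2.36). Matching on the 195c level gave 87.4 for formate dehydrogenases, 98.5 for oxygen and peroxide defence and 99.7 for stable RNA genes. By runs, that matching gave 52.5 for sulfate reduction (direction turned), 12.1 for ribosomal proteins, 17.2 for ATP synthase, 94.0 for formate dehydrogenases and 93.3 for prophage genes, all inside the range, and 99.9 for oxygen and peroxide defence and 99.8 for stable RNA genes. With a background taken off, stable RNA genes were at 99.8 (1st percentile) and 99.7 (5th percentile), and c-type cytochromes at 0.280 (5th percentile). Otherwise the cause was not tested.

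Of the genes named by rule, DFE_1482 (nifB) turned to -0.70 with the background of the 1st percentile taken off, and DFE_3318 (betaine aldehyde dehydrogenase) turned to -0.73 and, with the 5th percentile, to -1.42. For the genes named by rule, 697 values under alternatives fixed before and 278 under those added kept their side of the 2-fold rule; 4 and 2 moved inside it, 2 and 3 moved past it (DFE_0464 with a turn of sign, from 0.74 to -1.06), and 3 of those added reversed. Amino acid biosynthesis kept its side of the range in every alternative run. Depth limits such low genes, and no alternative replaces the missing replicates.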

Other observations

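Apart from DFE_1482 and nifH, the genes in this paragraph were chosen after their values were seen, and the tests in the weighing that follows were chosen after the data were seen. For the matching on the 195c level, by gene and by run, the bound was set before the percentiles were seen, but the general dependence on that level had been seen. Of 6 UspA genes with a mean CPM of at least 20, 4 were at least 2-fold higher in the EASW library and 1 lower (median log2 ratio 3.66), the lower one being DFE_3359, next to the hmc operon, at 2499 and 236 CPM. The main sigma factor gene rpoD (DFE_1057) stood at 2331 and 219 CPM. The 11 genes of the nitrogenase locus DFE_1482 to DFE_1492 had a median of 2.22, but summed to only 79.1 CPM in the 195c library and 328 CPM in the EASW library. That locus lay near the floor of the EASW library. With the 1st percentile taken off as a background, DFE_1482 turned to -0.70, while nifH (DFE_1492) had 3.72. The nifH ratio rose from 3.11 because 3.74 CPM per kb was also taken off its 195c level of 4.83 CPM per kb. That rise is not evidence of a larger difference. Of the 2 tmc operons, DFE_1444 to DFE_1447 had a median of -2.49 and DFE_1448 to DFE_1451 one of 0.35. Log2 ratios of neighbouring genes on the same strand correlated across genes with r = 0.611 (2328 pairs), against 0.172 for neighbours on opposite strands (762 pairs); genes are not independent replicates. Of 46 genes of the smaller replicon, 21 were at least 2-fold higher and 1 lower.

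Ferrous iron transport genes DFE_1865 and DFE_1866 were the lowest of all genes, while the second locus was not 2-fold different. Reads shared between the feoB copies would pull their ratios together, yet the log2 ratio of DFE_3369 exceeded that of DFE_1866 by 5.91, beyond both counting intervals. A general drop of genes abundant in 195c cannot be told apart: genes with a 195c CPM within 2-fold had a 2.5th percentile of -4.19 for DFE_1865 (223 genes, lowest -5.30) and -4.92 for DFE_1866 (21 genes, lowest -5.83), but the lowest of all genes lie below any such percentile. Repression by iron is a candidate explanation, but 0 libraries hold the rest of the medium fixed, so iron and the other differences between the cultures cannot be told apart.

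The medians of ribosomal proteins, ATP synthase and sulfate reduction were lower. With 1 value per run sulfate reduction turned direction (percentile 59.9), so its drop rests on genes that share operons. Ribosomal proteins kept their place in that alternative. ATP synthase lay at 2.95 there, just inside the range, but outside it among runs placed at random. A few abundant genes taking most of the reads do not account for the lower medians. The 10 most abundant took 12.9% of the 195c library and 11.7% of the EASW library. Leaving out the 10 genes of highest mean CPM and the stable RNAs shifts the log2 ratios of the other genes by -0.0312. A high 195c level stays open: random lists matched on it put the lists at percentiles 1.05, 2.02 and 0.735, but those lists ignore operons, and with 1 value per run the percentiles were 12.1, 17.2 and 52.5, so the lists and that level cannot be told apart; matched medians are low in part by construction, since that level is the denominator. Slower growth or a later growth phase in the EASW culture may lie behind the pattern, as a hypothesis: of 4 other growth-related sets, 3 lay at or below percentile 2.5 gene by gene, namely aminoacyl-tRNA ligases (0.02), translation factors and RNA polymerase (0.160) and DNA replication and division (2.37, with a random error of 0.152 that spans the bound), while envelope and fatty acid synthesis lay at 4.68. These sets are given only gene by gene, without the alternatives by run or by 195c level, so they leave shared operons and that level open too. Some values in these sets had been seen before the test, growth was not among the data, and the medium and growth state stay open together.

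Prophage and mobile element genes were higher, and a uniform background of reads in the EASW library could raise low genes. With a background of the 1st percentile taken off, the percentile of the list was 100, and with the 5th it was 99.99. These values cannot decide, since the background was also taken off the 195c library, which raises the ratios of genes low there. Members picked for large ratios, DFE_1723, DFE_1726, DFE_1737 and DFE_1746, stood at 98.4, 87.8, 204 and 46.8 CPM per kb in EASW. The backgrounds taken off there were 21.8 and 30.5 CPM per kb. Random lists matched on the 195c level had medians of 1.25 to 2.29, high in part by construction since that level is the denominator; the list was at percentile 99.97, but at 93.3 with 1 value per run, so a low 195c level cannot be told apart. Prophage induction is a hypothesis that these data leave open, since the number of DNA copies was not measured and 1 culture per medium was sequenced.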
